A study of Rattus norvegicus with 48 samples.

How the data were processed

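RNA was sequenced from brain tissue cut out of sections of rat motor cortex by laser capture microdissection, in which a laser cuts a chosen area from a section under a microscope. Regions were chosen by distance from a silicon electrode shank, per the labels' protocols. Near tissue lay within 100 µm of the shank and far tissue about 500 µm away. The tissue had been fixed before sectioning, and the library kit keeps the strand of the RNA, per the labels' protocols. The deposited values are counts of reads per gene, and the tables list only genes with at least 1 count in some library. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.6.1b, RSEM 1.3.1, DESeq2 and the rat genome build Rnor_6.0, with no role or order. RSEM gives estimated counts that need not be whole, and whether the authors rounded the deposited counts is not given in the sources used here. The counts were whole numbers and were used as deposited.

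The files identify genes by Ensembl IDs and do not pair them with names. The reference table used here (rat assembly GRCr8) held no Ensembl ID, so 0 of the 18997 distinct IDs matched a symbol. No name was inferred from an ID. At most 2 IDs that were higher and 2 that were lower are therefore given per comparison, and the 30 gene lists, the genes chosen by name and the marker levels fixed before the data were examined were not analysed here. The preset rule for genes to name asked for the most extreme log2 fold changes among genes with an adjusted p below 0.05, a mean log2 CPM (counts scaled to a common library total, and by TMM) of at least 3 and the same direction in every rat. It was applied to IDs, without its requirement of a symbol. Where groups held different rats, the same direction meant that the groups' values did not overlap. Reads shared between near-identical gene copies could not be examined without gene names or coordinates.

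The rat was the replicate. A rat with an implant in each hemisphere gave more than 1 library per distance, and its counts were summed per distance. Near and far tissue of the same rats was compared with the rat as a block, since the labels give the rat of every library. Within a time, the near and far deviations of a rat from their group means correlated between -0.0164 and 0.3 across genes. This correlation was above 0.1 in 7 of 15 rats, and in 11 of 15 rats near tissue correlated best with far tissue of the same rat. No pair of libraries within a group agreed within sampling noise (smallest chi-square per degree of freedom 49.14 over 120 pairs).

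Tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust estimation and the quasi-likelihood test), with Benjamini-Hochberg adjustment over the genes of a comparison. A gene was called at an adjusted p below 0.05. All adjusted p-values come from this test unless DESeq2 is named. Each ± after a log2 fold change is an approximate standard error, the fold change divided by the square root of the test's F statistic. That statistic uses a spread shared over the genes and groups of a fit, so the ± does not give the spread between rats. The near and far libraries of the 3 times shared a fit. Near tissue of different times, far tissue of different times, and each of these with naive tissue at the matching distance were compared in fits without a block. Implanted and naive libraries lie in separate tables, of 17317 and 17616 genes, and were compared over the 15936 genes in both. The labels number the libraries of these tables in different series, so in every comparison with naive tissue a batch difference and the implant cannot be told apart.

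The alternatives fixed before the data were examined were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, each rat left out in turn, no block, libraries not summed, only the groups compared in the fit, the rats of a time alone, naive libraries of both positions summed, subtraction of the naive difference between positions, and a minimum log2 fold change of 1. Alternatives added after seeing the data left out the 4 libraries with fewer than 6000 genes detected, or kept only genes with a mean log2 CPM of at least 6.

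The fits were tested on simulated counts with the real means, library sizes and estimated spread, in which 200 genes were drawn to change at each time. In the simulated near against far comparison at 24 h, over 14205 genes, edgeR called 6 genes, of which 1 was unchanged, and it called 7.81% of the genes changed 16-fold. At 1 week it called 17 genes, 0 of them unchanged, and 26.2% of those changed 16-fold. At 6 weeks it called 14 genes, 0 of them unchanged, and 21.5% of those changed 16-fold. It called 0% of the genes changed 4-fold at each of these 3 times. DESeq2 called 594 genes at 24 h, of which 561 were unchanged, 528 at 1 week with 479 unchanged, and 480 at 6 weeks with 432 unchanged. For naive 100 µm against 500 µm tissue, over 10902 genes, edgeR called 44 genes with 0 unchanged and DESeq2 called 346 with 277 unchanged.

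Library totals ran from 3363892 to 12844185 counts. A group with a count of 0 was given a floor of 3 counts over the group, and a fold against it is a lower bound that covers counting error only. Reads without molecular identifiers are not independent molecules.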

Results

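Gene expression was measured in rat motor cortex around implanted silicon electrode arrays, at 24 h, 1 week and 6 weeks after implantation. Tissue beside the shank (near, within 100 µm) was set against tissue about 500 µm away (far) and against cortex of naive rats without an implant. The data held 48 libraries. Of these, 36 came from 12 implanted rats, 3 at 24 h, 5 at 1 week and 4 at 6 weeks, with 6 near and 6 far libraries at each time. The other 12 came from 3 naive rats, 6 at each of the matching positions.

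Near libraries totalled 4910291 to 12709651 counts at 24 h, 3363892 to 8072159 at 1 week and 5933122 to 10308388 at 6 weeks. Far libraries totalled 6811666 to 7975492, 6173892 to 8030443 and 7505143 to 12844185 counts at these times. Naive libraries totalled 4209485 to 11555077 counts at 100 µm and 5185212 to 8253488 at 500 µm. The number of genes with at least 1 count ranged from 3062 to 16023 per library. It was below 6000 in 4 libraries, which were near tissue of rat 29 at 24 h, near tissue of rats 20 and 23 at 1 week and far tissue of rat 23 at 1 week. The same 2 genes were the most abundant in all 48 libraries. They held 30.68% of the counts in near tissue and 23.88% in far tissue of the implanted rats, a difference of 6.8 percentage points ± 5.58 (SD, n = 12). The share was higher near than far in 12 of 12 rats (two-sided exact sign-flip permutation test, p = 0.000488, the smallest these rats can give). The mean difference was 4.48 points at 24 h (3 of 3 rats, exact p = 0.25), 6.37 at 1 week (5 of 5, exact p = 0.0625) and 9.08 at 6 weeks (4 of 4, exact p = 0.125), each p being the smallest possible. In naive tissue the shares were 19.92% at 100 µm and 20.17% at 500 µm, with the share higher at 100 µm in 1 of 3 rats (exact p = 0.75).

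**Figure D1:**
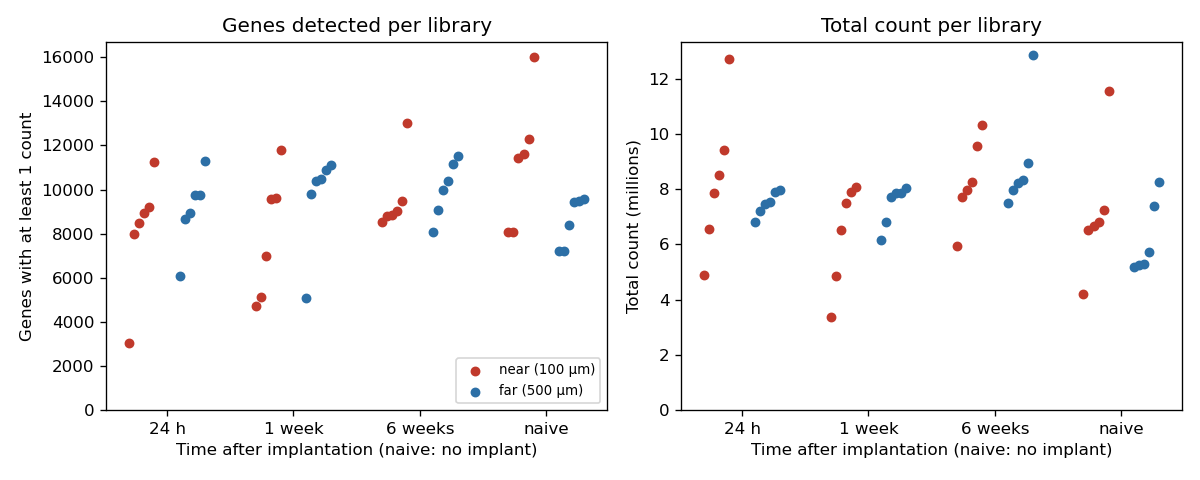
Genes with at least 1 count (left) and total count (right) of each library, by time and distance, with 1 point per library. Genes detected run from 3062 to 16023, and the lowest library, near tissue at 24 h, is not the one with the smallest total.

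**Figure D2:**
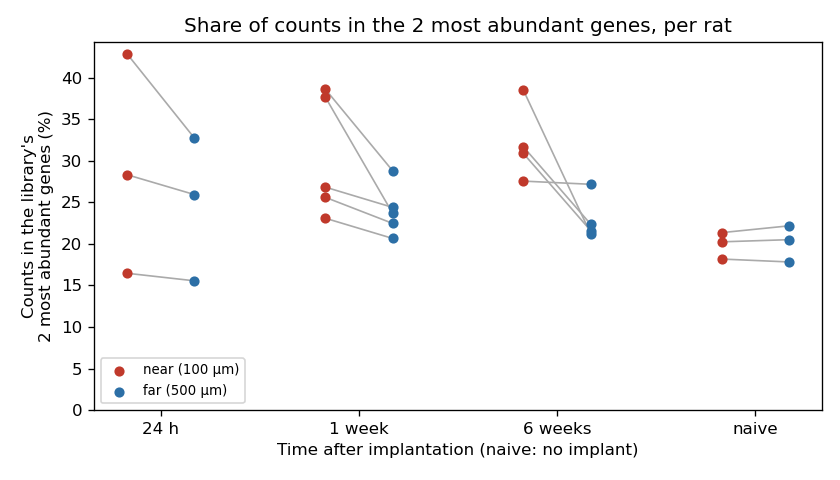
Percent of a library's counts in its 2 most abundant genes, averaged per rat, with a line joining near and far tissue of each rat. The near value lies above the far value in all 12 implanted rats, and in the 3 naive rats the mean difference was -0.244 percentage points.

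The comparison of near with far tissue asks which transcripts differed beside the implant. At 24 h, ENSRNOG00000057092 averaged 215 CPM ± 332 (SD, n = 3) near the implant and 1.65 ± 2.86 far from it. Its log2 fold change was 8.37 ± 2.03 (adjusted p = 0.0325), and its near values ran from 3.19 to 598 CPM. Rat 25 gave 9686 of its 10281 near counts, and far tissue had 0 counts in 2 of 3 rats. ENSRNOG00000058388 averaged 169 CPM ± 143 near and 2.58 ± 3.78 far, where 1 of 3 rats had 0 counts, with a log2 fold change of 7.81 ± 1.86 (adjusted p = 0.0286). The size of both fold changes rests on far counts at or near 0. In naive tissue, scaled within its own table, these genes averaged 3.79 and 9.68 CPM at 100 µm. ENSRNOG00000025463 was lower near the implant, at 56.7 CPM ± 52.8 against 215 ± 24.3 far (log2 fold change -2.49 ± 0.57, adjusted p = 0.0186). ENSRNOG00000003365 was also lower, at 69.5 CPM ± 75.4 near and 215 ± 45.8 far (log2 fold change -2.28 ± 0.55, adjusted p = 0.0325). Their naive levels at 100 µm were 223 ± 14.7 and 289.8 ± 104 CPM. The naming rule required the same direction in all 3 rats, so that agreement is no separate result for these 4 genes. For ENSRNOG00000003365 rat 30 had 156 CPM near and 169 far, a small difference.

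At 24 h 19 of 14399 genes were called near against far, 6 higher and 13 lower, and the same direction was seen in every rat for all 19. With DESeq2 size factors the calls were 13 higher and 9 lower, and without the 4 libraries of few detected genes they were 21 higher and 18 lower. In a fit of the rats of that time alone they were 12 higher and 0 lower, of which 3 were among the 19. The count was 2 without rat 25, 3 without rat 29, 30 without rat 30 and 0 without the rat as a block. ENSRNOG00000057092 and ENSRNOG00000058388 were each called in 5 of 11 alternatives, ENSRNOG00000025463 in 4 of 12 and ENSRNOG00000003365 in 3 of 12. Without rat 25, 29 or 30, the log2 fold change of ENSRNOG00000057092 was 10.38, 7.20 and 8.39 (adjusted p = 1, 0.788 and 0.113, with a range of 0.000128 to 1 over the alternatives). That of ENSRNOG00000058388 was 9.55, 7.02 and 6.45 (adjusted p = 0.199, 1 and 0.324, range 9.10e-05 to 1). For ENSRNOG00000025463 it was -1.60 and -2.52 without rat 25 or 29, neither called (adjusted p = 1 and 0.565, range 0.000979 to 1), and -3.34 without rat 30, called. For ENSRNOG00000003365 it was -1.84 and -1.50 without rat 25 or 29, neither called (adjusted p = 1 and 1, range 0.000844 to 1), and -3.25 without rat 30, called.

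At 1 week ENSRNOG00000008816 averaged 137 CPM ± 53.6 (SD, n = 5) near and 12.2 ± 12.5 far (log2 fold change 4.04 ± 0.74, adjusted p = 0.000399). ENSRNOG00000018087 averaged 313 CPM ± 146 near and 99.4 ± 124.5 far (log2 fold change 3.03 ± 0.68, adjusted p = 0.0414). Naive tissue at 100 µm held 7.18 CPM of the former and 18.5 of the latter. ENSRNOG00000009300 was lower near the implant, with 0 counts in 4 of 5 rats and 30.2 CPM in rat 9, against 74.9 CPM ± 45.0 far (adjusted p = 0.00209). ENSRNOG00000019382 averaged 18.8 CPM ± 24.3 near and 84.5 ± 29.9 far (log2 fold change -3.86 ± 0.91, adjusted p = 0.00959). In naive tissue ENSRNOG00000009300 averaged 27.3 CPM at 100 µm and 28.8 at 500 µm, where 1 of 3 rats had 0 counts. ENSRNOG00000019382 averaged 57.3 CPM at 100 µm and 99.2 at 500 µm there, the same direction without an implant. Each of these genes moved the same way in all 5 rats, as the naming rule required. With DESeq2 size factors the 2 higher genes were no longer called (log2 fold changes 4.26 and 3.29, adjusted p = 0.474 and 0.517). Over the alternatives the adjusted p ran from 7.83e-07 to 0.755 for ENSRNOG00000008816 and from 8.19e-08 to 0.8615 for ENSRNOG00000018087. With the naive difference between positions subtracted ENSRNOG00000008816 was not called, and that difference has no bounded fold because naive tissue at 500 µm held 0 counts of it. Without the 4 libraries of few detected genes ENSRNOG00000019382 was not called (log2 fold change -2.49, adjusted p = 0.414, with a range of 0.000145 to 1 over the alternatives), nor without rat 10, 20 or 22 (log2 fold changes -2.76, -2.82 and -4.58, adjusted p = 0.305, 0.0792 and 0.0591). ENSRNOG00000009300 was not called without rat 23 (adjusted p = 0.0773, with a range of 1.66e-12 to 0.3515). Its fitted log2 fold change was -8.88 without rat 23 and -10.05 with all rats, values that rest on the 0 counts near the implant.

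At 1 week 57 of 14399 genes were called, 8 higher and 49 lower near the implant, and the same direction was seen in every rat for 44 of the 57. The balance of directions was not stable: DESeq2 size factors gave 20 higher and 21 lower, and leaving out the 4 libraries gave 14 higher and 14 lower. No low-count filter gave 22 higher and 21 lower. The excess of lower calls remained with the DESeq2 Wald test (271 higher, 1033 lower), without rat 9 (7 and 66) and with the rats of that time alone (7 and 17). The median log2 fold change of all tested genes was -0.66 with TMM and -0.47 with DESeq2 size factors. It was -0.13 among the 2175 genes with a mean log2 CPM of at least 6, -0.24 without the 4 libraries, -0.44 without rat 10, -0.23 without rat 20 and -1.04 without rat 9, so the shift itself was not stable. Without rat 10 there were 19 calls (9 higher, 10 lower), without rat 20 there were 31 (20 higher, 11 lower) and without rat 22 there were 31 (14 higher, 17 lower), while without rat 23 there were 7 higher and 53 lower. The count was 6 without the rat as a block.

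At 6 weeks ENSRNOG00000008816 averaged 81.5 CPM ± 61.5 (SD, n = 4) near and 0.61 ± 1.16 far, a log2 fold change of 8.70 ± 0.99 (adjusted p = 3.41e-10). Far tissue held 40 counts of it in all and 0 in 2 of 4 rats, so the size of this fold change rests on counts at or near 0. ENSRNOG00000030118 averaged 83.5 CPM ± 27.95 near and 12.95 ± 9.91 far (log2 fold change 3.24 ± 0.60, adjusted p = 0.000165). ENSRNOG00000007219 was lower near the implant, at 399 CPM ± 141 against 826 ± 153 (log2 fold change -1.11 ± 0.22, adjusted p = 0.000591). ENSRNOG00000048682 was lower as well, at 959 CPM ± 146 against 1759 ± 323 (log2 fold change -0.87 ± 0.17, adjusted p = 0.000648). In naive tissue at 500 µm ENSRNOG00000008816 had 0 counts in 3 of 3 rats, and at 100 µm it ranged from 0 to 19.65 CPM. With DESeq2 size factors ENSRNOG00000008816 kept a log2 fold change of 8.77 but was not called (adjusted p = 0.0890, with a range of 4.97e-22 to 1 over the alternatives). ENSRNOG00000030118 was called in 7 of 13 alternatives, and not without rat 2 (log2 fold change 2.29, adjusted p = 0.386, with a range of 1.465e-05 to 1). With the naive difference between positions subtracted its log2 fold change was -0.80, not called, where its naive level at 500 µm was as low as 0.079 CPM. ENSRNOG00000007219 was called in 7 of 13, and not without rat 11 or rat 17 (log2 fold changes -1.11 and -0.87, adjusted p = 0.294 and 0.4405, with a range of 0.00059 to 1). ENSRNOG00000048682 was called in 5 of 13, and not without rat 11 or rat 2 (log2 fold changes -0.72 and -0.95, adjusted p = 1 and 0.0577, with a range of 0.00158 to 1) or by DESeq2 (adjusted p = 0.0533).

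At 6 weeks 11 of 14399 genes were called, 9 higher and 2 lower, and the same direction was seen in every rat for 10 of the 11. The count of called genes was 23 without rat 11, 24 without rat 2 and 41 without the 4 libraries of few detected genes. These libraries belong to the other times of the shared fit. The count was 1 without the rat as a block and 0 in a fit of the rats of that time alone.

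**Figure D3:**
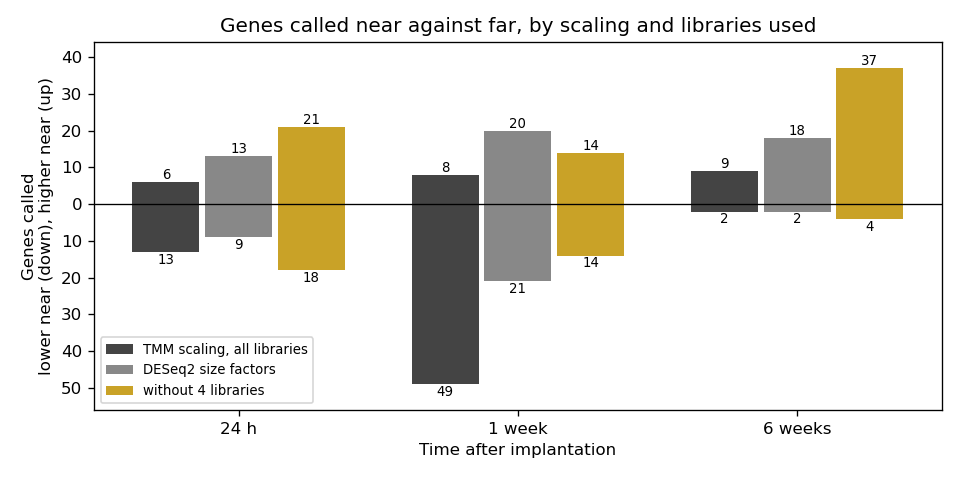
Number of genes called higher (up) and lower (down) near the implant than far from it at each time, with TMM scaling, with DESeq2 size factors, and without the 4 libraries of fewer than 6000 genes detected. At 1 week the 8 higher and 49 lower genes became 20 and 21, or 14 and 14.

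**Figure D4:**
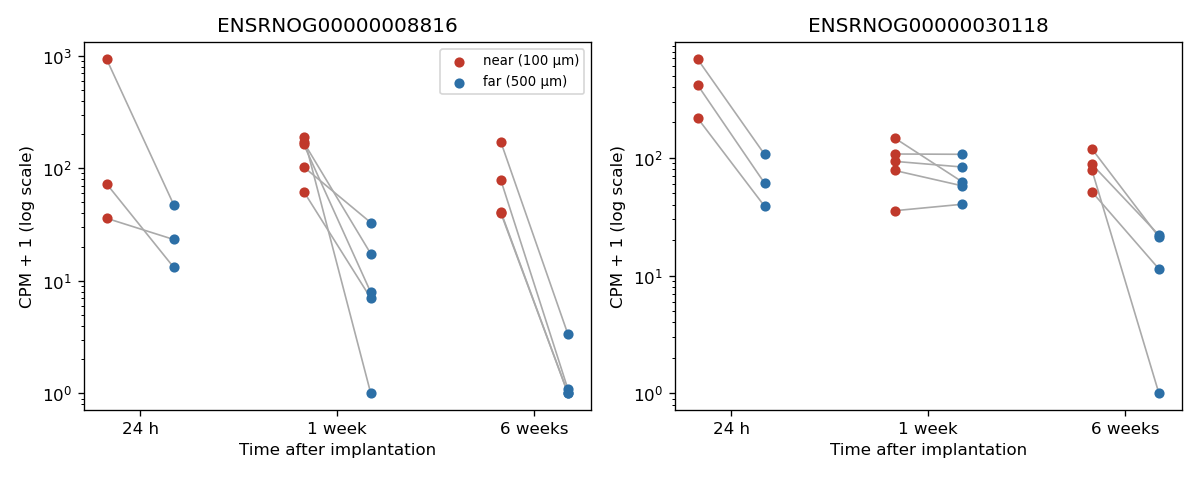
CPM plus 1, on a log axis, of 2 genes in near and far tissue, with a line joining the values of each rat. At 6 weeks the near value of ENSRNOG00000008816 averaged 81.5 CPM and its far value 0.61 CPM.

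In all, 74 genes were called near against far at some time and 0 at all 3 times. Different rats were used at each time. Of the genes called higher near the implant, 2 were shared between 24 h and 1 week, 3 between 1 week and 6 weeks and 1 between 24 h and 6 weeks. Of those called lower, 6, 1 and 0 were shared. The 3 lists came from a fit with shared spread per gene, so no chance overlap is given. The change of the near-far difference was tested directly. From 24 h to 1 week edgeR called 0 of 14399 genes, with 258 at an unadjusted p under 0.05, and DESeq2 called 417. The edgeR count was 7 without rat 10, 4 without rat 20 or rat 22, 1 without rat 25 and 4 without the 4 libraries of few detected genes. From 1 week to 6 weeks 4 genes were called, all with a higher near-far difference at 6 weeks. The median change of all tested genes was 0.63 on the log2 scale, in the same direction. The shared direction of the 4 genes is therefore not particular to them. ENSRNOG00000019382 changed by 5.33 ± 1.21 on the log2 scale (adjusted p = 0.0399), with 115 CPM ± 36.5 near and 42.9 ± 16.25 far at 6 weeks. ENSRNOG00000000463 changed by 2.34 ± 0.51 (adjusted p = 0.0195), with 395 CPM ± 59.7 near and 155 ± 53.4 far at 6 weeks. The count of 4 became 0 without rat 19, 2 without rat 17, 8 without rat 10 or rat 9, 12 without rat 22 and 0 without the rat as a block. Of the 8, 4, 3 and 4 genes called without rat 10, 11, 2 or 20, 0 were among the 4 called with all rats. ENSRNOG00000000463 was called in 6 of 16 alternatives and lost the call without any of rats 10, 11, 17, 19, 2, 20 and 22 (adjusted p = 0.158, 0.617, 0.0799, 0.167, 1, 0.0567 and 0.173), while its change stayed between 2.19 and 2.50 without these rats. ENSRNOG00000019382 was called in 5 of 16 and lost the call without any of rats 10, 11, 17, 19, 2 and 20 (adjusted p = 0.243, 0.380, 0.114, 0.167, 0.501 and 0.0567), with a change between 4.24 and 5.59. Over all alternatives the adjusted p ran from 2.595e-09 to 1 and from 0.0008125 to 1 for these genes.

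Near tissue was also compared between times. ENSRNOG00000046834 was higher at 1 week, at 348 CPM ± 232 (SD, n = 5) against 43.5 ± 32.5 at 24 h (n = 3; log2 fold change 3.00 ± 0.56, adjusted p = 0.0103). ENSRNOG00000016043 was higher too, at 317 CPM ± 178 against 64.85 ± 26.7 (log2 fold change 2.29 ± 0.49, adjusted p = 0.03205). ENSRNOG00000030118 was lower at 1 week, at 87.3 CPM ± 38.9 against 426 ± 233 (log2 fold change -2.29 ± 0.47, adjusted p = 0.0103). ENSRNOG00000005299 was lower, at 2155 CPM ± 254 against 4984 ± 2223 (log2 fold change -1.21 ± 0.22, adjusted p = 0.0024). In the order given, these were called in 9, 6, 7 and 10 of 15 alternatives. They were among 6 genes called of 12799, 4 higher and 2 lower at 1 week. The count was 1 without rat 10, 0 without rat 20, 3 without rat 23, 16 without rat 25 and 2 without the 4 libraries of few detected genes. The median log2 fold change of all tested genes was -0.18 with TMM and -0.07 with DESeq2 size factors.

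From 1 week to 6 weeks 1 gene was called in near tissue, ENSRNOG00000049829 (adjusted p = 0.0230), which had 7996 counts over 3 of 4 rats at 6 weeks and 0 counts in all 5 rats at 1 week. It lay outside the naming rule because the rats of the 2 times overlapped and was named after its value was seen. The count was 0 without any of rats 10, 11, 19, 20, 22, 23 and 9. In far tissue edgeR called 0 of 12995 genes between 24 h and 1 week, with 546 at an unadjusted p under 0.05, and DESeq2 called 196. Between 1 week and 6 weeks it called 0, with 661 at an unadjusted p under 0.05, and DESeq2 called 129.

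Near tissue was set against naive tissue at 100 µm, in which batch and implant cannot be told apart. At 24 h ENSRNOG00000030118 averaged 428.5 CPM ± 231 (SD, n = 3) against 15.3 ± 13.4 in naive tissue (n = 3; log2 fold change 4.81 ± 0.69, adjusted p = 3.845e-06). ENSRNOG00000018681 averaged 287 CPM ± 152.5 against 14.1 ± 7.07 (log2 fold change 4.35 ± 0.79, adjusted p = 0.00149), and it was called in 14 of 14 alternatives. ENSRNOG00000060332 was lower, at 21.35 CPM ± 16.95 against 308 ± 85.6 (log2 fold change -3.85 ± 0.85, adjusted p = 0.03375), and was also called lower at 1 week and 6 weeks (adjusted p = 0.00429 and 0.00121). At 1 week ENSRNOG00000002919 averaged 2094 CPM ± 774 (n = 5) against 56.0 ± 34.4 (log2 fold change 5.22 ± 0.68, adjusted p = 0.0109). ENSRNOG00000046834 averaged 353 CPM ± 230.1 against 9.60 ± 9.20 (log2 fold change 5.19 ± 0.80, adjusted p = 0.00429). Each of these was called in 15 of 16 alternatives. At 6 weeks the same genes averaged 1520 CPM ± 768 and 257 ± 144 (n = 4), with adjusted p = 0.0465 and 0.0258 against the same naive rats. ENSRNOG00000002919 already ran from 502 to 1664 CPM at 24 h, when it was not called. ENSRNOG00000060522 was lower at 6 weeks, at 4.23 CPM ± 2.19 against 486 ± 149.6 (adjusted p = 0.0362). Its near level was also low at 24 h (3.37 to 14.4 CPM) and at 1 week (0 to 16.3 CPM). It was called lower in near tissue at 1 week and in far tissue at 1 and 6 weeks as well, so its low level is not particular to 6 weeks or to near tissue. At 24 h ENSRNOG00000030118 was called in 13 and ENSRNOG00000060332 in 7 of 14 alternatives. At 6 weeks ENSRNOG00000002919 was called in 8, ENSRNOG00000046834 in 11 and ENSRNOG00000060522 in 10 of 15.

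The counts of calls against naive 100 µm tissue, over 13834 genes, were 8 at 24 h (6 higher, 2 lower), 17 at 1 week (6 higher, 11 lower) and 6 at 6 weeks (2 higher, 4 lower). DESeq2 size factors gave 12 higher and 2 lower, 24 higher and 9 lower, and 3 higher and 3 lower. The median log2 fold change of all tested genes was -0.17, -0.30 and -0.17 with TMM and 0.00, -0.03 and -0.01 with DESeq2 size factors. At 24 h the count was 18 without rat 25, 30 without rat 30 and 18 without naive rat n3. At 1 week it was 7 without rat 10, 31 without rat 20, 7 without naive rat n2, 30 without n3 and 11 without n5. At 6 weeks it was 3 without rat 11, 2 without rat 17, 2 without rat 19 and 18 without n3.

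Far tissue was set against naive tissue at 500 µm under the same confounding of batch and implant. ENSRNOG00000055311 had 0 counts in far tissue of all 3 rats at 24 h and all 5 at 1 week, and 189 CPM ± 75.8 (SD, n = 3) in naive tissue. It was at least 2660-fold lower at 24 h and at least 2790-fold lower at 1 week (adjusted p = 5.15e-07 and 6.93e-10). In near tissue it also had 0 counts at 24 h and 1 week, against 171 CPM ± 159.5 in naive tissue at 100 µm, and it had 5 counts in near and 4 in far tissue at 6 weeks. ENSRNOG00000020762 averaged 20.3 CPM ± 13.6 at 1 week (n = 5) and 29.7 at 6 weeks (n = 4, from 16.3 to 46.2), and had 0 counts in the 3 naive rats at 500 µm. It was at least 246-fold higher at 1 week and at least 360-fold higher at 6 weeks (adjusted p = 0.0295 and 0.0332). ENSRNOG00000010966 averaged 76.4 CPM ± 43.1 at 1 week against 4.67 ± 4.12 (adjusted p = 0.0473). ENSRNOG00000005228 averaged 130.5 CPM ± 45.7 at 6 weeks against 25.55 ± 7.88 (adjusted p = 0.0342). At 24 h far tissue already held 15.8 to 40.5 CPM of ENSRNOG00000020762, 31.2 to 47.6 of ENSRNOG00000010966 and 49.5 to 94.5 of ENSRNOG00000005228, none of them called at that time. ENSRNOG00000020762 was called in 6 of 15 alternatives at 1 week and 6 of 14 at 6 weeks, ENSRNOG00000010966 in 6 of 15 and ENSRNOG00000005228 in 7 of 15. ENSRNOG00000055311 was called in 13 of 13 at 24 h and 15 of 15 at 1 week.

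The counts of calls in far against naive tissue, over 13369 genes, were 1 at 24 h (lower), 17 at 1 week (4 higher, 13 lower) and 8 at 6 weeks (3 higher, 5 lower). At 24 h the count was 2 without rat 25 or rat 30, 4 without naive rat n2, 9 without n3 and 5 without n5. At 1 week it was 5 without rat 10 or rat 22, 11 without rat 23 and 4 without rat 9. At 6 weeks it was 2 without rat 11 or rat 19, 5 without rat 17, 3 without rat 2, 13 without n2 and 18 without n3 or n5.

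Naive tissue at 100 µm and 500 µm was compared to show what position gave without an implant. edgeR called 0 of 11839 genes, with 600 at an unadjusted p under 0.05, and DESeq2 called 1357. The edgeR count was 9 without rat n2 and 8 without n3. Genes detected differed by 2703 ± 1142 (SD, n = 3) between the positions, with more at 100 µm in 3 of 3 rats (two-sided exact sign-flip permutation test, p = 0.25, the smallest 3 rats can give).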

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

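The tests of library size, of genes detected by distance, of that difference against naive rats and of the share of the 2 most abundant genes by distance were chosen only after the result was seen, and so was the alternative without the 4 libraries of fewer than 6000 genes detected.

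Single samples lay far from the others of their group in 5 of 32 groups examined. Chance alone gives about 1 in 20 for library measures, a rate that does not hold for the 2 IDs below, whose other values were at or near 0. In far tissue at 1 week, the left hemisphere of rat 23 had 5089 genes detected and the next lowest library 9798. In near tissue at 6 weeks, the left hemisphere of rat 19 had 13028 genes detected and the next highest 9494. In far tissue at 6 weeks, the right hemisphere of rat 19 totalled 12844185 counts and the next highest 8965534. ENSRNOG00000009300 had 30.19 CPM in near tissue of rat 9 at 1 week and 0 in the other 4 rats. ENSRNOG00000008816 had 2.351 CPM in far tissue of rat 17 at 6 weeks, and the next highest rat had 0.0896. By the direct test of the difference, the near-far difference changed between 1 week and 6 weeks for 4 genes, a count that was 0 without rat 19, 2 without rat 17, 8 without rat 10 or rat 9 and 12 without rat 22.

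Genes detected differed widely between libraries, from 3062 to 16023. Library size is argued against as the whole cause, since after thinning every library to the smallest total the highest number was still 5.32 times the lowest. Distance from the implant could contribute: genes detected were lower near than far in 9 of 12 rats, by -1134 ± 2138 on average (near minus far, SD), with a two-sided exact sign-flip p of 0.0889. In naive rats the difference was 2703, and the differences of implanted and naive rats differed (exact permutation p = 0.0132), which goes with an effect of the implant but also holds the batch, so distance stays open. RNA quality and the amount of tissue per library were not measured in the data used here and stay open.

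At 1 week 8 genes were called higher and 49 lower near the implant. Without the 4 libraries of few detected genes 14 were higher and 14 lower, so these libraries may contribute to the excess of lower calls. This alternative removes the only near library of rat 20, so with the rat as a block that rat adds nothing to the difference. For rat 23 it sets near tissue of the left hemisphere against far tissue of the right. It is therefore not separate from the run without rat 20, which also ended the excess (20 higher, 11 lower). Leaving out rat 23, which holds 2 of the 4 libraries, did not end it (7 higher, 53 lower). Leaving out rat 10 (9 higher, 10 lower) or rat 22 (14 higher, 17 lower), which hold none of them, ended it too. Leaving out rat 9, which also holds none, kept it (7 higher, 66 lower). These libraries are therefore not singled out. With DESeq2 size factors 51.2% of the calls were lower, just above the bound of at most 50% set before the result was seen. The DESeq2 Wald test, which also scales by size factors, kept the excess (271 higher, 1033 lower). Scaling stays open as well. A biological excess of lower transcripts near the implant at 1 week cannot be told apart from the scaling.

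DESeq2 called more genes than edgeR in all 16 comparisons. With near and far labels swapped in 1 naive rat DESeq2 still called 560 genes at most, against 1357 with the real labels, a value between the bounds set in advance. In simulated near and far tissue at 24 h, 561 of its 594 calls were unchanged genes, so part of its calls on these libraries may be false. The simulated counts used the spread estimated by edgeR and held no differences between rats. They cannot show what share of the real DESeq2 calls is false. No biological explanation was tested for this pattern.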

How the results depend on the processing

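The alternatives without the 4 libraries of few detected genes and with a mean log2 CPM of at least 6 were chosen only after the result was seen. Counts below are genes called by edgeR unless DESeq2 is named, and where no cause is given the cause was not tested. Of 549 values of named IDs under the alternatives, over 39 pairs of an ID and a comparison, 331 kept their direction and their call, 215 kept their direction and lost the call, and 3 reversed. The 3 arose with the naive difference between positions subtracted. For ENSRNOG00000030118 at 6 weeks the value was -0.80. Its naive level at 500 µm averaged 4.11 CPM with a minimum of 0.079, so this value too rests on a naive level near 0. For ENSRNOG00000008816 the fitted values were -5.05 (1 week) and -0.31 (6 weeks), but naive tissue at 500 µm held 0 counts of this gene in 3 of 3 rats, so they depend on an unbounded naive fold and show no change of direction.

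With the DESeq2 Wald test near against far gave 529 genes at 24 h, 1304 at 1 week and 330 at 6 weeks. The change of this difference gave 417 from 24 h to 1 week and 405 from 1 to 6 weeks. Near tissue gave 255 between 24 h and 1 week and 160 between 1 and 6 weeks, and far tissue 196 and 129. Near against naive tissue gave 400, 308 and 183 at the 3 times, far against naive tissue 680, 777 and 659, and naive positions 1357.

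For near against far, DESeq2 size factors gave 20 at 6 weeks. A log2 fold change of at least 1 gave 35 at 1 week and 7 at 6 weeks. Unsummed libraries with the implant as block gave 1 and 4, and 0 for the change from 1 to 6 weeks. No block gave 0, 6 and 1 at the 3 times and 0 for that change. The rats of a time alone, which are fewer samples, gave 12, 24 and 0. Subtraction of the naive difference gave 6 at 24 h, 7 at 1 week and 15 at 6 weeks, of which 0, 2 and 0 were among the 19, 57 and 11 called without it. No low-count filter gave 30 at 6 weeks and 1 for the change from 24 h to 1 week. A mean log2 CPM of at least 6, which tests fewer genes, gave 0, 4 and 1 at the 3 times and 1 for the change from 1 to 6 weeks. Without the 4 libraries the counts were 39, 28 and 41, and 4 and 7 for the changes.

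Between times, the higher CPM minimum gave 0 for near tissue from 24 h to 1 week and 0 from 1 to 6 weeks. The groups compared alone gave 1 and the set without the 4 libraries 2 for near tissue from 24 h to 1 week. No filter gave 5 for near tissue from 1 to 6 weeks, 1 for far tissue from 24 h to 1 week and 7 for far tissue from 1 to 6 weeks.

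Against naive tissue, where batch and implant cannot be told apart, DESeq2 size factors gave 14 near at 24 h and 33 near at 1 week. Unsummed libraries gave 36, 32 and 15 near at the 3 times, and 7 far at 24 h and 7 at 1 week. No filter gave 27, 40 and 14 near, and 4 far at 24 h and 14 at 6 weeks. The higher CPM minimum gave 5 near at 24 h and 6 at 1 week, and 2 far at 1 week and 4 at 6 weeks. The groups compared alone gave 11 near at 1 week and 19 at 6 weeks, and 5, 11 and 18 far. Naive libraries of both positions gave 4 near at 24 h. Without the 4 libraries 16 were called near and 5 far at 24 h. For naive positions no filter gave 1 and the higher CPM minimum 1.

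With each rat left out in turn, near against far ranged from 2 (without rat 25) to 30 (without rat 30) at 24 h, 19 (rat 10) to 73 (rat 9) at 1 week and 9 (rat 19) to 24 (rat 2) at 6 weeks. The changes ranged from 0 to 7 (rat 10) and from 0 (rat 19) to 12 (rat 22). Near tissue ranged from 0 (rat 20) to 16 (rat 25) between 24 h and 1 week and from 0 to 1 between 1 and 6 weeks, and far tissue stayed at 0 in both. Near against naive ranged from 6 to 30 (rat 30), 7 (rat 10 or n2) to 31 (rat 20) and 2 (rat 17 or 19) to 18 (n3). Far against naive ranged from 1 to 9 (n3), 4 (rat 9) to 22 and 2 (rat 11 or 19) to 18 (n3 or n5), and naive positions from 0 to 9 (n2). The 30 gene lists, the genes chosen by name and their alternatives were not run, because no ID could be paired with a name. On simulated counts edgeR called 0% of genes changed 4-fold near against far, while many genes called in the real data changed by less, with a median absolute log2 fold change of 1.75, 1.16 and 1.11 among the genes called at the 3 times. The simulation therefore gives no limit on the size that could be called.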

Other observations

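The tests of whether directions recur and of the share of the 2 most abundant genes were chosen only after the result was seen.

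The 19 genes called near against far at 24 h had the same direction at 1 week (19 of 19) and at 6 weeks (19 of 19), in other rats. Over both times this was 38 of 38, where the median of 512 swaps of near and far within rats was 19 (one-sided exact permutation p = 0.00391). At 1 week alone the exact p was 0.0312, the smallest possible, and at 6 weeks it was 0.125. The 19 genes were called in a fit whose spread per gene came from the real near and far labels of all times. Swapped labels are therefore not on an equal footing with the real ones, and these p-values cannot decide whether directions recur. Of all tested genes, 67.69% were lower near at 1 week and 53.55% at 6 weeks, as were 13 of the 19. Genes called at 1 week had the same direction in 52 of 57 at 24 h and 52 of 57 at 6 weeks, and those called at 6 weeks in 8 of 11 at 24 h and 10 of 11 at 1 week. These other counts were not tested by swaps. A near-far difference shared with the later times is a candidate explanation for the genes called at 24 h, which these counts cannot decide.

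The 2 most abundant genes, the same in all 48 libraries, held a larger share of counts near than far in 12 of 12 rats (exact permutation p = 0.000488, the smallest possible), and the difference between implanted and naive rats had an exact permutation p of 0.044 over 455 regroupings. Distance from the implant may go with a higher share, but the difference from naive rats also holds the batch. What these genes are was not analysed here, and RNA quality stays open.

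Other splits of the samples were counted for each comparison, the real split included. Some counts used a random part of the possible splits. Near against far these were 21 of 126 at 1 week and 21 of 32 at 6 weeks. For the changes they were 21 of 56 from 24 h to 1 week and 21 of 126 from 1 to 6 weeks. Near and far tissue from 1 to 6 weeks used 100 of 126 each. Near against far at 24 h, 5 of 10 splits gave at least the real 19 genes (highest other 59), and 10 splits are too few for a share under 0.05. At 1 week 5 of 21 gave at least 57 (highest other 959), and at 6 weeks 2 of 21 gave at least 11 (highest other 16). Some of these splits left near and far tissue of a rat together, so these shares cannot decide whether chance gave the calls. In a fit with the rat as a block, a rat left together adds nothing to the difference tested. A split that parts 1 rat, as the one with 959 genes at 1 week, thus tests the near-far difference of that rat alone. Splits that part only the same rat repeat 1 test. The other splits with more calls than the real one at 24 h and 1 week left near and far tissue of some rats together: at 1 week those with 959, 211, 67 and 67 genes parted 1 or 3 of 5 rats, and at 24 h those with 37 or 59 parted 1 of 3. Other splits that also left rats together called 0 genes. The fit has the rat as a block, so the splits that part every rat are the ones to compare with. Among these the real one was the highest of 16 at 1 week (57, the others from 2 to 12) and of 4 at 24 h (19, the others from 3 to 6), but 16 and 4 splits are too few for a share under 0.05. At 6 weeks 2 of 8 were as large (11, highest other 16), also too few for such a share.

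Where edgeR called 0 genes, every split is as large by construction, so the count of splits says nothing about chance. This holds for the change from 24 h to 1 week (21 of 21 splits, highest other 67; 258 genes at an unadjusted p under 0.05 in edgeR, 417 by DESeq2). It also holds for far tissue from 24 h to 1 week (56 of 56, highest other 4; 546 and 196) and from 1 to 6 weeks (100 of 100, highest other 2; 661 and 129). For the change from 1 to 6 weeks 11 of 21 splits gave at least 4 (highest other 12). For near tissue from 24 h to 1 week 4 of 56 gave at least 6 (highest other 12), and from 1 to 6 weeks 12 of 100 gave at least 1 (highest other 2). Chance was not excluded in these last 3 comparisons.

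Against naive tissue the share of splits with at least the real count was under 0.05 for near tissue at 1 week (2 of 56 splits with at least 17, highest other 27) and 6 weeks (1 of 35 with at least 6, highest other 3). It was also under 0.05 for far tissue at 1 week (1 of 56 with at least 17, highest other 3) and 6 weeks (1 of 35 with at least 8, highest other 4). These shares were not corrected for the number of comparisons, which share the same naive rats, so they do not exclude chance. The batch is confounded with these splits and stays open. At 24 h the 10 splits are too few for a share under 0.05: the real counts were 8 near (1 split as large, highest other 1) and 1 far (3 splits as large, highest other 1). For naive positions the 10 splits are too few as well, and with a real count of 0 all 10 are as large by construction (10 of 10, highest other 20; 600 genes at an unadjusted p under 0.05 in edgeR, 1357 by DESeq2).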
